A study of Homo sapiens with 8 samples.

How the data were processed

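Poly(A) RNA sequencing was analysed for 8 libraries of 2 human acute myeloid leukaemia cell lines, NOMO-1 and MOLM-13, in 4 groups of 2 libraries. In each line, cells carrying 1 short hairpin RNA against ALKBH5 (shALKBH5) were set against cells carrying a non-targeting hairpin (shNS). Groups and replicate numbers came from the sample labels. The labels' texts differ on the treatment: the series design text gives puromycin selection for 4 days, while the sample protocols give 1 week and speak of a virus against FTO and of drug treatments, which no sample label lists. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

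The authors deposited a single table of TPM, RSEM's length-scaled share of transcripts, for 26830 gene symbols. The unit was read from the values: each deposited TPM column sums to 1000000 within rounding. Per the submitters' processing notes, STAR, RSEM and the build GRCh38 were used; versions, annotation and strand setting are not given in the sources used here. TPM keeps no depth, so the depth of each library is unknown and no counting interval is given. TPM is also a share: a rise in abundant transcripts of a library lowers the values of all other genes there. An exact 0 in such a table can be a failed estimate. Within a group, 13, 17, 11 and 27 genes (NOMO-1 shNS, NOMO-1 shALKBH5, MOLM-13 shNS, MOLM-13 shALKBH5) were listed at 0 in 1 library and at 10 TPM or more in the other, so genes at 0 are described as listed at 0, with each library's value. Values of multi-copy families (ribosomal protein genes with processed pseudogenes, HLA-DRB genes, MIR3648 and small nuclear RNA copies, histone genes) and of microRNA or small nucleolar RNA genes that lie inside other genes are uncertain, because reads can be assigned to a copy or to the host gene.

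Genes with at least 1 TPM in at least 2 libraries were kept (14302 genes). limma 3.58.1 in R 4.3.3 was run on log2(TPM + 1) with a mean for each group over all 8 libraries, which left 4 residual degrees of freedom (limma added 2.29 prior degrees of freedom), empirical Bayes moderation with an intensity trend, two-sided tests, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are therefore on the log2(TPM + 1) scale and understate changes of low genes. The spread of each gene is pooled over the 4 groups, although the MOLM-13 shALKBH5 libraries stood furthest apart. MOLM-13 p-values may thus be too small and NOMO-1 p-values too large. Fitted alone, MOLM-13 passed 1684 genes in place of 5972 and NOMO-1 9123 in place of 6242. 5 comparisons were made: knockdown in NOMO-1, knockdown in MOLM-13, the mean of both effects, their difference (NOMO-1 minus MOLM-13) and the control libraries of NOMO-1 minus those of MOLM-13. The design planned a count test in case the table held counts. Reads cannot be recovered from TPM, so the planned count-model alternative was not run. Overlaps of calls used Fisher's exact test. No control library is shared by the 2 lines, but the estimate of spread of each gene is.

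25 gene lists were fixed before the data were examined: m6A machinery without ALKBH5, p53 targets, MYC targets in ribosome assembly and growth, mitosis, DNA replication, homologous recombination and Fanconi repair, monocytic differentiation, azurophil granule, MLL-fusion leukaemia programme, pro-apoptotic and anti-apoptotic genes, interferon-stimulated genes, NF-kB and inflammatory genes, ATF4 stress response, ER chaperones and ER-stress genes, glycolysis, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, immediate-early genes, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, and erythroid, megakaryocyte, lymphoid and epithelial markers. 21 lists had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Genes named in the text followed a rule also fixed before the data were examined, apart from members of lists chosen afterwards and IFIT1 and CXCL10. The rule takes 10 fixed genes; for each line and for the mean, the 10 largest changes in each direction among genes past the threshold whose groups did not overlap and whose larger group mean was at least 5 TPM; the 3 members with the smallest p of each list that passed or had at least 3 members past the threshold; the 5 smallest p in each direction for the difference; and the 5 largest folds in each direction between controls. A few genes that the rule names are not reported here.

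Coordinates come from GENCODE release 29 (GRCh38), in which 23794 of the symbols matched exactly 1 gene name. RefSeq gene types were used to class RNAs, and 23987 symbols matched a current RefSeq symbol. The test was run on simulated data for 13578 genes. For a simulated NOMO-1 knockdown, among changed genes of at least 5 TPM, 39 of 68 with a log2 change of 1 were called. With a log2 change of 2 they were 63 of 72. Of genes without a change at any level, 10 of 13383 were called, and camera called 0 of 40 random lists. The simulation changed few genes, gave each gene the same spread in all libraries and drew genes independently. The real libraries and lists differ in this, so its rates of false calls do not carry over to them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

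Alternatives tried were other pseudocounts (0.1 and 5), no filter and a stricter filter on low values (mean of at least 5 TPM), median-of-ratios and quantile scaling, each line fitted alone, no intensity trend, robust moderation, library weights, a replicate block, and each library left out in turn. Protein-coding genes alone, rescaled, were added after the data were examined. Scaling by median-of-ratios factors moved the median of all genes by -0.14 in NOMO-1, 0.24 in MOLM-13, 0.06 for the mean, -0.44 for the difference and -0.25 between controls, in log2 units. Counts over all genes are therefore given under both scalings, and list counts for a part of the lists only.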

Results

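ALKBH5 removes the m6A mark, a methyl group on adenosines, from RNA. Its level was lowered with a short hairpin RNA in NOMO-1 and MOLM-13, leukaemia cell lines that carry an MLL fusion gene, and polyadenylated RNA was sequenced in 8 libraries. Each of the 4 groups held 2 libraries (n = 2 throughout): NOMO-1 shNS, NOMO-1 shALKBH5, MOLM-13 shNS and MOLM-13 shALKBH5. The depth of the libraries is unknown, since the deposited values are TPM. On the log2 scale, over genes with a mean of at least 10 TPM, the SD of the difference between the libraries of a group was 0.107 in NOMO-1 shNS, 0.17 in NOMO-1 shALKBH5, 0.15 in MOLM-13 shNS and 0.581 in MOLM-13 shALKBH5, whose libraries stood furthest apart.

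ALKBH5 itself (chromosome 17, 18183078 to 18209954, GRCh38) was lower in every knockdown library than in every control library of its line. In NOMO-1 it stood at 70.4 and 71.8 TPM in the controls and at 15.1 and 14.2 TPM after knockdown, 4.86 times lower by group mean. In MOLM-13 the controls had 45.7 and 45.8 TPM and the knockdown libraries 9.45 and 7.35 TPM, 5.45 times lower. The log2 fold change was -2.21 (SE 0.13, limma adjusted p = 0.00032) in NOMO-1 and -2.32 (SE 0.13, adjusted p = 0.00019) in MOLM-13.

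**Figure D1:**
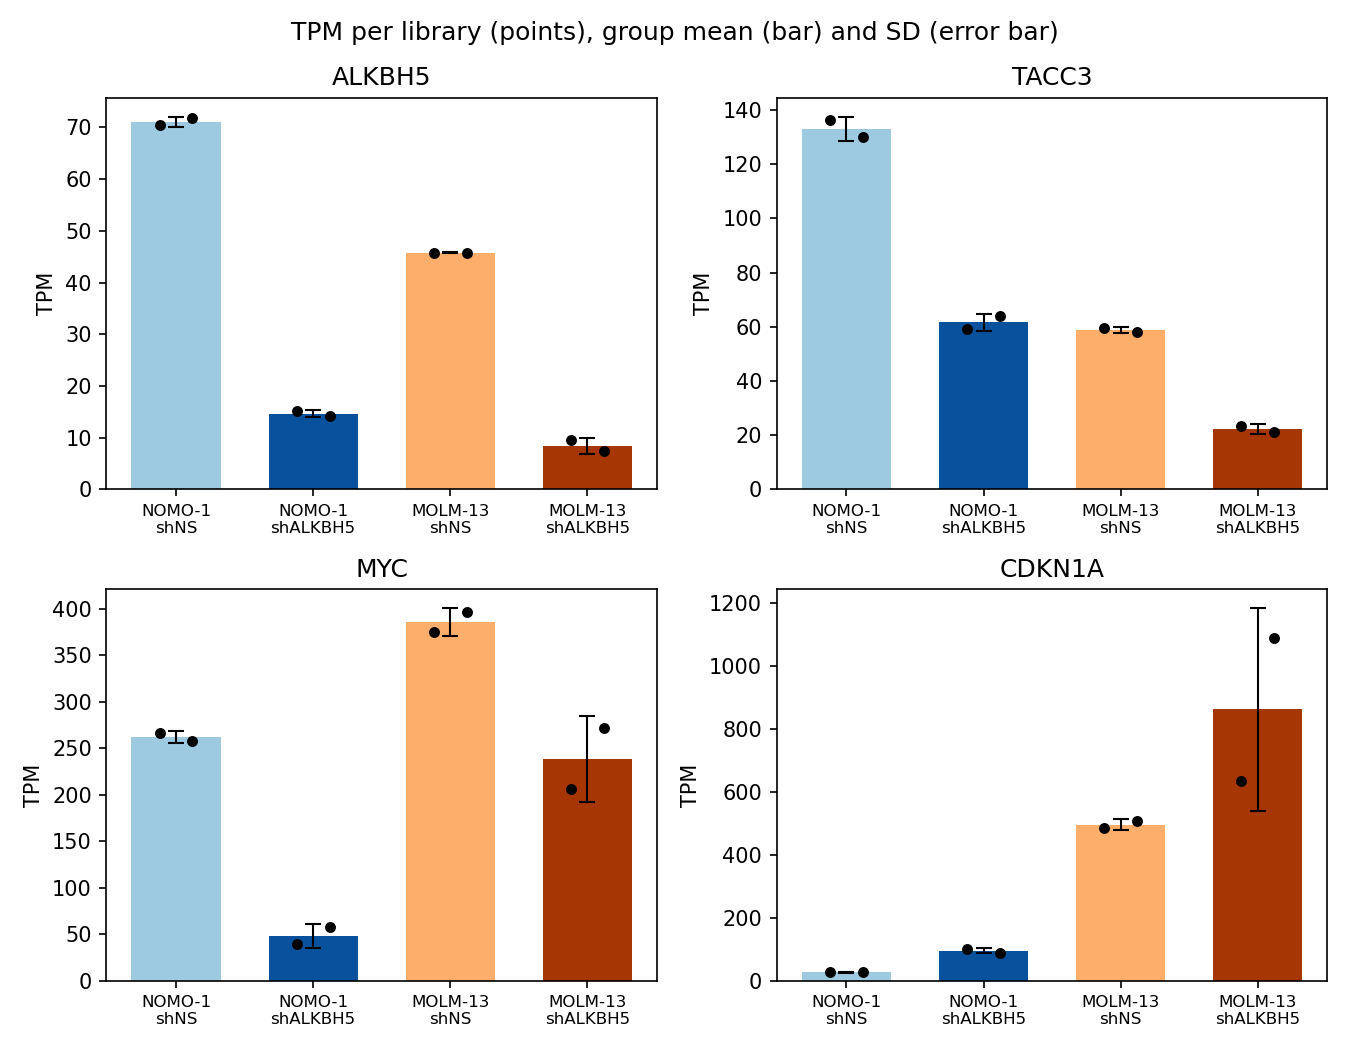
TPM of ALKBH5, TACC3, MYC and CDKN1A (vertical axes, from 0) in the 4 groups (horizontal axes). Points are libraries, bars group means and error bars the SD of 2 libraries; ALKBH5 fell from a mean of 71.1 to 14.6 TPM in NOMO-1 and from 45.7 to 8.4 TPM in MOLM-13, and the CDKN1A libraries of MOLM-13 shALKBH5 lie far apart.

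The first comparison asked which transcripts changed when ALKBH5 was lowered in NOMO-1. Cell division genes fell together: all 39 members of the mitosis list and 37 of 42 DNA replication genes were lower (0 higher in either list), as were 24 of 32 genes of homologous recombination and Fanconi repair (1 higher). On the log2 scale, the mitosis genes CDCA3, ECT2 and NEK2 fell by 2.29, 2.89 and 2.23. MCM2, a subunit of the replicative helicase, fell by 1.72, and RAD51AP1, a recombination factor, by 2.7. MYC, a growth-promoting transcription factor, fell from 262 ± 6.3 to 48.1 ± 13 TPM (SD, n = 2; log2 fold change -2.45, SE 0.2, adjusted p = 0.00053). Of its targets in ribosome assembly and growth, 23 of 42 fell and 4 rose, and among those that fell were TCOF1 (-2.2), BOP1 (-1.12) and EXOSC5 (-0.89). Genes of the endoplasmic reticulum's protein folding machinery rose: 15 of 20 members were higher and 0 lower, including DNAJB9 (from 12.4 ± 0.58 to 141 ± 2.8 TPM, adjusted p = 0.00024), the chaperone HSPA5 (log2 fold change 1.57) and the ubiquitin ligase SYVN1 (2.16). Of the 10 genes in the azurophil granule list, tied to myeloid granules though not all encode granule proteins, 8 rose and 0 fell. CFD was at 1.57, MS4A3 at 1.84 and CTSG at 1.72. The cytosolic ribosomal protein list held 34 of 63 members that fell and 0 that rose, with RPS10 at -2.38, RPL5 at -1.73 and RPS23 at -1.83.

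With limma's camera at the preset correlation, the adjusted p was 4.5e-24 for mitosis, 1e-20 for DNA replication and 1.6e-12 for homologous recombination and Fanconi repair. It was 3.9e-06 for MYC targets, 1.3e-05 for ER chaperones, 0.00018 for the azurophil granule and 1.4e-13 for ribosomal proteins. With an estimated correlation none of the 21 lists passed: adjusted p = 0.5 for mitosis, DNA replication, ER chaperones and azurophil granule, 0.56 for homologous recombination and Fanconi repair, and 0.78 for MYC targets and ribosomal proteins. Adjusted over the list alone, 39 mitosis genes, 37 DNA replication genes, 26 recombination genes, 23 MYC targets and 38 ribosomal protein genes were lower, and 15 ER chaperones and 9 azurophil granule genes were higher.

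The ETS transcription factor genes ETV5 (from 83.9 ± 2.5 to 2.99 ± 1.9 TPM, adjusted p = 0.00072) and ETV4 (from 16.4 ± 0.16 to 0.18 ± 0.13 TPM, adjusted p = 0.00024) had the largest falls in NOMO-1 among genes not listed at 0. The growth-factor-induced gene EGR1 (log2 fold change -3.69) and the chemokine gene CCL2 (-3.68) also fell, as did KIF14, MBNL3, NUCKS1 and CASC5 (-3.32, -3.13, -3.02 and -2.99). KLHL23 and EEF1E1 also fell, and each was listed at 0 in NOMO-1 shALKBH5 replicate 3 and at 1.39 and 1.1 TPM in replicate 2. TP53INP2, an autophagy gene, rose from 24.4 ± 0.4 to 259 ± 11 TPM, and NUPR1, a stress-induced gene, from 8.7 ± 2.2 to 87.7 ± 13 TPM. MIR22HG (3.78), SELM (3.69) and SIGLEC1 (3.79, adjusted p = 0.039), a macrophage lectin, rose as well, and VCX, listed at 0 in 1 control and at 4 TPM in the other, reached 19.5 and 21.8 TPM. The SIGLEC1 call ended when any library other than those of MOLM-13 shALKBH5 was left out, and its adjusted p reached 0.15 over the alternatives. MIR6727, MIR4639 and MIR635 were listed at 0 in both controls. In replicates 2 and 3 of the knockdown MIR6727 had 7.17 and 14.4 TPM, MIR4639 5.68 and 17.1 TPM and MIR635 4.53 and 13.6 TPM, and the MIR635 call ended in 9 alternatives, median-of-ratios scaling among them (adjusted p up to 0.19).

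Among the fixed genes, TACC3, a spindle protein, fell (-1.1, adjusted p = 0.00062), while the cell cycle inhibitor CDKN1A (1.78, adjusted p = 0.0021) and the histone demethylase KDM4C (1.24, adjusted p = 0.00081) rose. FTO, the other m6A demethylase, did not pass (0.02, adjusted p = 0.96), nor did the methyltransferase genes METTL3 (-0.35, 0.059) and METTL14 (-0.14, 0.59) or the m6A reader YTHDF2 (0.03, 0.92). Of 20 alternatives, METTL3 passed in 6 and METTL14 in 5. AXL stayed under 1 TPM (0.1, 0.91). The other lists did not pass camera. Of 25 p53 targets 9 were higher and 4 lower (DDB2 -1.68, ZMAT3 1.79, SESN2 1). Monocytic differentiation had 9 higher and 3 lower of 29 (CD68 1.67, S100A8 1.93, FCGR2A 1.79), and the MLL-fusion programme 5 and 5 of 20 (BCL2 -2.29, CDK6 -1.01, HOXA7 -1.3). The ATF4 response had 7 higher and 5 lower of 26 (DDIT3 2.18, DDIT4 -1.45). Pro-apoptotic genes had 4 and 3 of 20 (TNFRSF10A -1.25, BAD 0.82, BAK1 0.83) and anti-apoptotic genes 3 and 2 of 9 (BCL2L2 1.13, BCL2L1 0.78). In metabolism, glycolysis had 4 higher and 6 lower of 20 (SLC2A1 -1.32) and cholesterol synthesis 8 and 2 of 20 (MVD 1, CYP51A1 0.81, IDI1 0.89). Oxidative phosphorylation had 1 and 7 of 44 (SDHB -1.62, NDUFS1 -0.74), with camera adjusted p = 0.1, and 0.00092 with median-of-ratios scaling. The m6A machinery had 1 higher and 3 lower of 18 (IGF2BP2 -2.2, YTHDF3 1.1, CBLL1 -0.68), with adjusted p = 0.1, and 0.047 with median-of-ratios scaling. Few members passed among immediate-early genes (0 and 2 of 14), interferon-stimulated genes (1 and 1 of 36), NF-kB genes (0 and 1 of 20) and lymphoid markers (1 and 1 of 5). The spread between the MOLM-13 libraries enters these tests, and with NOMO-1 fitted alone 4 immediate-early genes were higher and 7 lower, 8 and 7 interferon-stimulated genes, and 10 and 4 NF-kB genes. That fit gave 11 higher and 5 lower pro-apoptotic genes, 5 and 3 anti-apoptotic genes, 13 and 8 genes of the ATF4 response, 12 and 9 monocytic genes, 12 and 7 p53 targets, 7 and 8 glycolysis genes, 11 and 4 cholesterol synthesis genes, 4 and 7 genes of the m6A machinery, 6 and 12 of oxidative phosphorylation and 8 and 25 MYC targets. With median-of-ratios scaling the counts in NOMO-1 were 6 higher and 7 lower for p53 targets, 2 and 9 for the m6A machinery, 1 and 17 for oxidative phosphorylation, 2 and 9 for glycolysis, 5 and 3 for cholesterol synthesis, 0 and 27 for MYC targets, 12 and 0 for ER chaperones and 0 and 26 for ribosomal proteins. For the MLL-fusion programme, pro-apoptotic, interferon-stimulated and NF-kB genes the median was above 0 while camera pointed downwards.

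Over all genes tested, 6242 of 14302 passed the threshold in NOMO-1, 4097 higher and 2145 lower (65.6% higher), and 1391 rose and 745 fell by at least 2-fold. With median-of-ratios scaling 7120 passed, 3608 higher and 3512 lower (50.7% higher), and 5471 genes passed under both scalings in the same direction. The count ranged from 3490 without NOMO-1 shNS replicate 3 to 9745 without MOLM-13 shALKBH5 replicate 1.

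The second comparison asked the same question in MOLM-13. Cell division genes fell here too: 39 of 39 mitosis genes, 42 of 42 DNA replication genes and 30 of 32 recombination and Fanconi genes were lower and 0 were higher. The log2 fold change was -3.58 for UBE2C, a ubiquitin-conjugating enzyme of mitosis, -3.33 for GINS2, -3.47 for DTL and -3.07 for CHEK1, a checkpoint kinase. The proliferation marker MKI67 went from 116 ± 1.1 to 2.3 ± 1.5 TPM (adjusted p = 0.00024), and the cell cycle kinase CDK1 from 89.8 ± 1.4 to 2.03 ± 2.5 TPM (adjusted p = 0.0011). KIAA0101, TYMS, CCNE2, MYBL2, NCAPG, E2F8 and ASPM were at -4.92, -4.6, -4.46, -4.43, -4.4, -4.33 and -4.3. Genes of the MLL-fusion programme fell, 17 of 20 members (0 higher), among them ZNF521 (-2.21), CDK6 (-2.12), MEIS1 (-1.55) and BCL2 (-2.22). Of 42 MYC targets 30 fell and 0 rose, with UNG at -3.14, NPM1 at -1.55 and TCOF1 at -1.12; with median-of-ratios scaling 19 were lower and 4 higher. MPO, the peroxidase of azurophil granules (chromosome 17, 58269856 to 58280935), fell from 420 ± 51 to 17.9 ± 2.1 TPM (log2 fold change -4.48, SE 0.15, adjusted p = 0.00011), 23.5 times lower. In the same list 6 of 10 genes rose, among them PRTN3 (1.52) and CFD (1.01), and CTSG fell as well (-0.77).

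Camera gave adjusted p = 5.7e-19 for mitosis, 2.2e-17 for DNA replication, 1.4e-10 for recombination and Fanconi repair, 5e-06 for the MLL-fusion programme, 6.6e-05 for MYC targets and 0.0039 for the azurophil granule. Cholesterol synthesis also passed (8 higher and 0 lower of 20, adjusted p = 9.8e-05), with MVD at 1.08, FDFT1 at 0.52 and MSMO1 at 0.61. The m6A machinery passed downwards (0 higher and 12 lower of 18, adjusted p = 0.0068), with IGF2BP2 at -0.81, YTHDC1 at -0.72 and CBLL1 at -1.09. Upwards passed p53 targets (8 higher and 4 lower of 25, adjusted p = 0.0038) and cytosolic ribosomal proteins (20 higher and 7 lower of 63, adjusted p = 1.4e-05). The p53 targets with the smallest p were GDF15, which rose (1.08), and CCNG1 and FAS, which fell (-1.19 and -0.97). The ribosomal protein genes with the smallest p all fell: RPS10 (-1.62), RPL13A (-1.14) and RPL5 (-1.33). With an estimated correlation the adjusted p was 0.47 for mitosis, DNA replication, recombination, MLL-fusion programme, azurophil granule, cholesterol synthesis and p53 targets, and 0.72 for MYC targets, m6A machinery and ribosomal proteins. Adjusted over the list alone, 39, 42, 31, 17, 33 and 14 genes were lower in mitosis, DNA replication, recombination, MLL-fusion programme, MYC targets and m6A machinery. By the same adjustment 20, 9, 8 and 6 genes were higher in ribosomal proteins, p53 targets, cholesterol synthesis and azurophil granule. The ribosomal protein call ended without MOLM-13 shALKBH5 replicate 3 (adjusted p = 0.22), with quantile scaling (0.43) and with fry (0.5). That of the azurophil granule ended in the same settings (0.15, 0.067 and 0.067), that of p53 targets with fry (0.12) and that of the m6A machinery with quantile scaling (0.084). With median-of-ratios scaling 16 p53 targets were higher and 2 lower, 14 and 0 cholesterol synthesis genes, 22 and 4 ribosomal protein genes, and 0 and 8 genes of the m6A machinery. The median of ribosomal protein genes against the controls was 0.05 in MOLM-13 shALKBH5 replicate 1 and 0.45 in replicate 3. With MOLM-13 fitted alone 0 of these genes were higher and 4 lower. Fitted alone, MOLM-13 had 20 recombination genes, 12 MLL-fusion genes, 8 MYC targets and 1 gene of the m6A machinery lower, and 1 p53 target and 1 cholesterol synthesis gene higher, against 37 mitosis and 35 DNA replication genes lower. Against the controls the m6A machinery had medians of -0.38 in replicate 1 and -0.73 in replicate 3. Those of cholesterol synthesis were 0.26 and 0.38. The median-of-ratios factor of replicate 3 was 0.64, against 0.929 and 0.932 in the controls, so a typical gene was lower there too.

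Interferon-stimulated genes were high in MOLM-13 shALKBH5 replicate 1 and not in replicate 3. IFIT1 stood at 70.7 and 0.35 TPM in these 2 libraries against 1.96 and 1.43 TPM in the controls, ISG15 at 215 and 16.2 against 11.6 and 12.8, and CXCL10 at 130.5 and 0.15 against 0.45 and 0.36. In the list as a whole, 0 of 36 members passed limma's test (1 at an unadjusted p under 0.05), although camera gave adjusted p = 7.3e-05 (0.72 with an estimated correlation). With median-of-ratios scaling 5 members were higher and 0 lower, and camera gave adjusted p = 0.011. The median log2 difference of the list from the controls was 2.66 in replicate 1 and -0.62 in replicate 3. A typical gene was also lower in replicate 3, whose median-of-ratios factor was 0.64, against 0.929 and 0.932 in the controls. The members with the smallest p were BST2, STAT2 and ISG15. The NF-kB and inflammatory list behaved likewise, with 0 of 20 members past limma's threshold (1 at an unadjusted p under 0.05) and camera adjusted p = 0.0064 (0.72 with an estimated correlation, 0.13 with median-of-ratios scaling); CCL4 stood at 97.6 and 0.42 TPM.

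**Figure D2:**
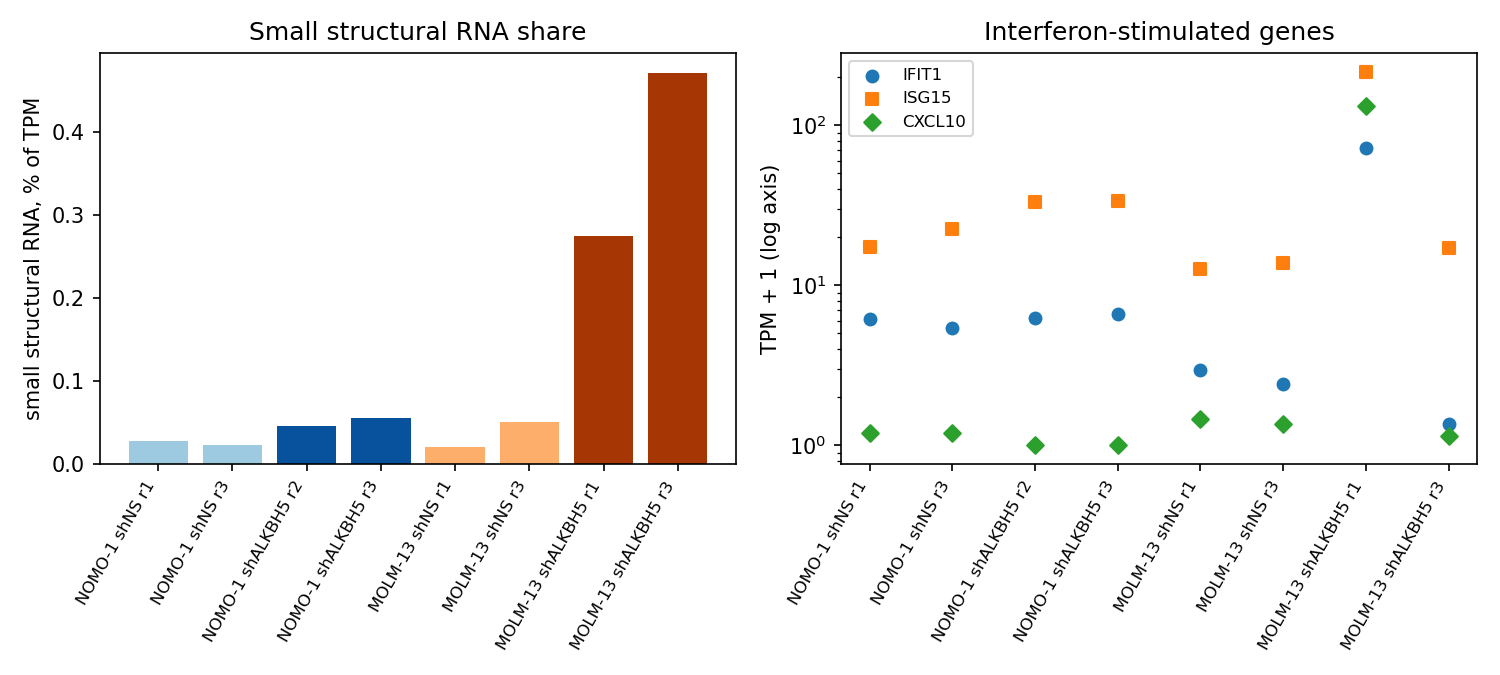
Left, share of small structural RNA in the TPM of each library (vertical axis, percent); right, IFIT1, ISG15 and CXCL10 in each library (vertical axis, TPM + 1, log axis). Both MOLM-13 shALKBH5 libraries, at 0.274% and 0.471%, hold the most small structural RNA, and the interferon-stimulated genes are high in replicate 1 of that group.

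Structural RNAs without a poly(A) tail were higher in both MOLM-13 shALKBH5 libraries. RNA5-8S5, a ribosomal RNA, was listed at 0 in every other library and at 1621 and 4046 TPM there, RN7SK went from 74.3 and 61 to 1284 and 2747 TPM (adjusted p = 0.00063), and RMRP and SNORD3A rose by 3.96 and 3.43. RNU4-1 and SNORD64 were listed at 0 in both MOLM-13 controls and stood at 11.2 and 19.2 TPM and at 15.4 and 4.71 TPM after knockdown. The share of small structural RNA in the library was 0.0208% and 0.0504% in the controls and 0.274% and 0.471% after knockdown, and that of ribosomal RNA transcripts went from 2.28% and 1.69% to 3.75% and 7.35%. MIR3648-1 and MIR3648-2, near-identical copies, were each listed at 0 in MOLM-13 shNS replicate 3 and stood at 7.93 and 22.9 TPM after knockdown. SERPINB2 (3.88) and HLA-DRB5 (3.38) were the other genes with the largest rises.

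TACC3 fell (-1.36, adjusted p = 0.00034) in MOLM-13. MYC went from 386 ± 15 to 239 ± 46 TPM (-0.71, adjusted p = 0.034), and CDKN1A from 495 ± 17 to 861 ± 320 TPM (0.75, adjusted p = 0.048). FTO fell by 0.73 (adjusted p = 0.013) and METTL14 by 0.94 (0.0093). METTL3 was at -0.4 (0.043) and YTHDF2 at -0.48 (0.039). Over the alternatives the adjusted p reached 0.31 for MYC and 0.84 for METTL3, both with median-of-ratios scaling, and 0.17 for YTHDF2, 0.18 for CDKN1A, 0.11 for FTO and 0.093 for METTL14. KDM4C was at -0.02 (0.91) and, with median-of-ratios scaling, past the threshold at 0.3. AXL was at 0.09 (0.92), with 9.37 and 1.92 TPM in replicates 1 and 3 of the knockdown against 4.39 and 3.95 TPM in the controls. Without MOLM-13 shNS replicate 1 the adjusted p was 0.12 for MYC, 0.18 for CDKN1A, 0.074 for FTO and 0.15 for METTL3. The other lists did not pass. ER chaperones had 6 higher and 6 lower of 20 (CANX -1.05, SEL1L -0.94, CALR -0.76) and monocytic differentiation 5 and 4 of 29 (CEBPB 1.27, CD68 0.92, FCGR2A 0.99). Pro-apoptotic genes had 5 and 5 of 20 (APAF1 -1.37, BAK1 0.76), anti-apoptotic genes 0 and 4 of 9 (XIAP -0.63), and the ATF4 response 4 and 11 of 26 (SHMT2 -1.35, VLDLR -1.05). Glycolysis had 2 higher and 9 lower of 20 (HK1 1.46, PDK1 -1.42). Oxidative phosphorylation had 6 and 8 of 44 (NDUFS1 -1.09, SDHB -1.2), with adjusted p = 0.23, and 23 higher and 6 lower with median-of-ratios scaling (0.011, upwards). By that scaling 10 ER chaperones were higher and 4 lower, 8 and 2 monocytic genes, 9 and 5 pro-apoptotic genes, 6 and 10 genes of the ATF4 response and 6 and 5 glycolysis genes. Several of these lists differed between the MOLM-13 shALKBH5 libraries. In replicates 1 and 3 the median log2 difference from the controls was 0.33 and -0.4 for monocytic genes. It was 0.11 and -0.17 for oxidative phosphorylation, 0.1 and -0.25 for pro-apoptotic genes and -0.22 and -0.8 for anti-apoptotic genes. The ATF4 response was at -0.21 and -0.75 and glycolysis at -0.16 and -0.51. A typical gene was also lower in replicate 3, whose median-of-ratios factor was 0.64 (0.929 and 0.932 in the controls). With MOLM-13 fitted alone, monocytic genes had 2 higher and 0 lower, oxidative phosphorylation 0 and 2 and pro-apoptotic genes 0 and 1. That fit gave 0 and 1 anti-apoptotic genes, 2 and 4 of the ATF4 response, 1 and 2 glycolysis genes and 0 and 3 ER chaperones. Immediate-early genes had 0 higher and 3 lower of 14 (EGR1 -4.17, IER2 -1.18, FOSB -1.87). Their median against the controls was 0.2 in replicate 1 and -1.5 in replicate 3. Of 20 alternatives, the FOSB call ended in 7 and the IER2 call in 3. Lymphoid markers had 1 higher and 0 lower of 5. For monocytic, pro-apoptotic and oxidative phosphorylation genes the median was below 0 while camera pointed upwards. Erythroid, megakaryocyte and epithelial markers had 1, 3 and 2 members with at least 1 TPM in 2 libraries. Over all markers of these lists the highest values were 14 TPM (HBB, listed at 0 in every other library), 12.5 TPM (GP1BA) and 1.62 TPM (KRT8), all in MOLM-13 shALKBH5 libraries. The highest lymphoid marker was NKG7, at 376.8 TPM in NOMO-1 shNS replicate 1. Mitochondrially encoded mRNAs were not analysed here.

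In MOLM-13, 5972 genes passed the threshold, 1513 higher and 4459 lower (25.3% higher), and 345 rose and 1767 fell by at least 2-fold. With median-of-ratios scaling 7271 passed, 3749 higher and 3522 lower (51.6% higher), and 5019 passed under both scalings in the same direction. With MOLM-13 fitted alone 1684 passed (384 higher, 1300 lower), and leaving out a library gave from 2665 (without MOLM-13 shNS replicate 1) to 9439 (without MOLM-13 shALKBH5 replicate 1).

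**Figure D3:**
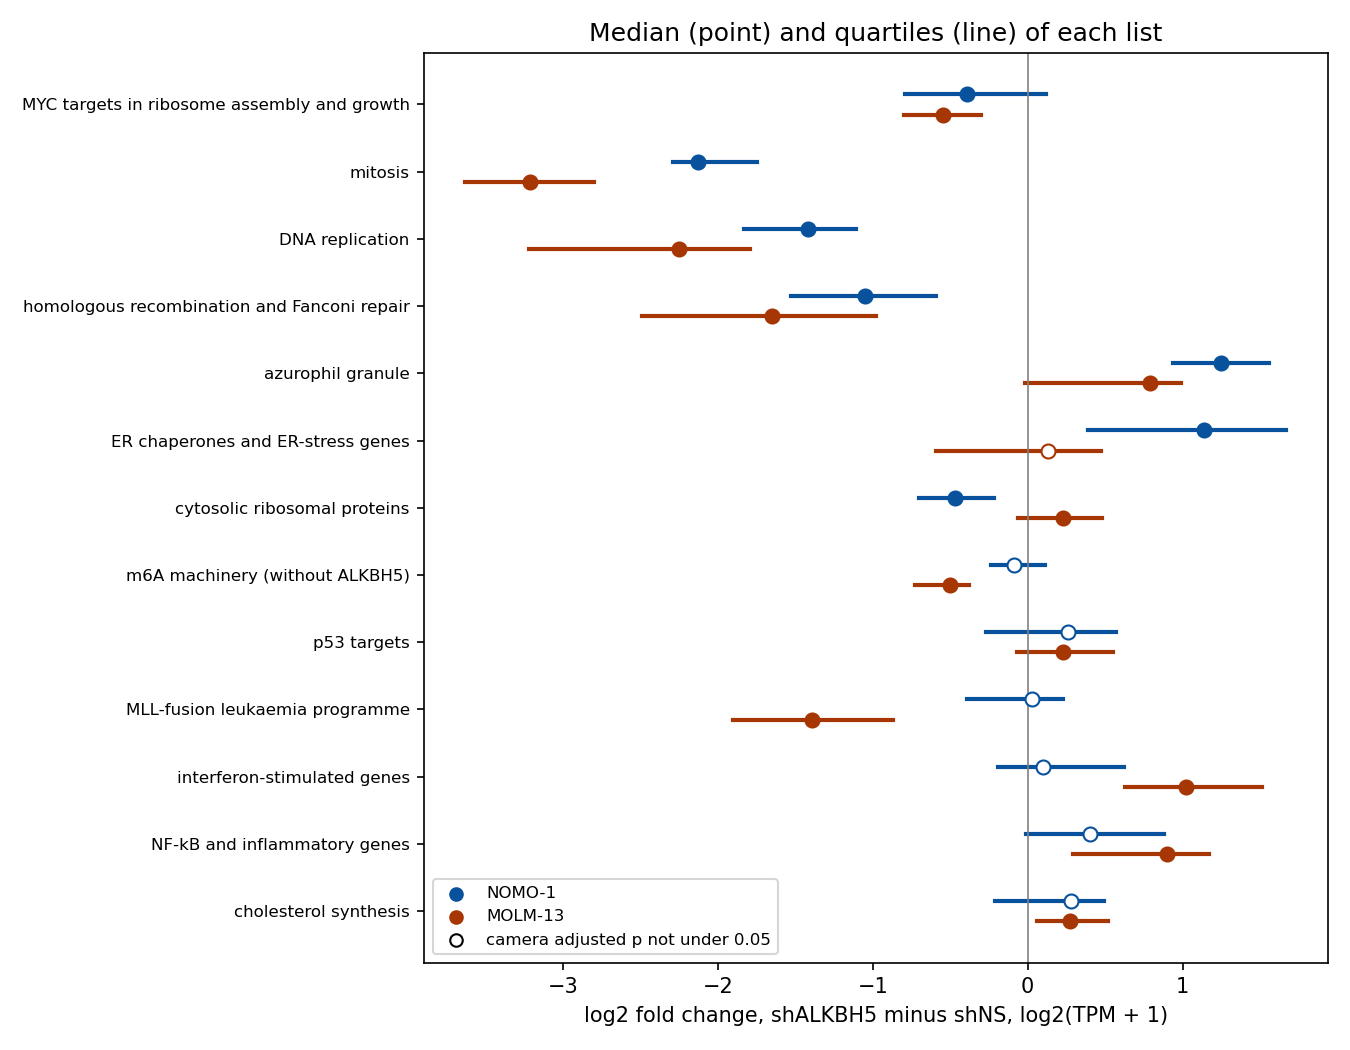
Median (points) and quartiles (lines) of the log2 fold change of list members, shALKBH5 minus shNS on log2(TPM + 1), for lists past the camera threshold in either line (vertical axis), with open points where not past it. Mitosis genes have medians of -2.13 in NOMO-1 and -3.21 in MOLM-13, and -2.31 and -2.95 with median-of-ratios scaling.

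Taking both lines, the effects on the 14302 genes had a Pearson correlation of 0.49 across genes, which are not independent replicates. The mean effect passed for 7256 genes (3433 higher, 3823 lower; 47.3% higher), and for 8480 with median-of-ratios scaling (4487 higher, 3993 lower). Genes past the threshold in both lines numbered 906 higher (433.4 expected for independent lists, odds ratio 4.49, Fisher's exact test p = 1.6e-159) and 1481 lower (668.8 expected, odds ratio 6.87). Another 541 were higher in NOMO-1 and lower in MOLM-13 (1277 expected), and 50 the other way (226.9 expected); with median-of-ratios scaling these were 342 and 332. The same-direction overlap of 2387 genes was 3680 with median-of-ratios scaling. Fisher's test takes genes as independent, and the calls of both lines share the estimate of spread of each gene. Its p therefore does not measure how well the lines reproduce each other. Among genes whose groups did not overlap in either line, the largest mean rises were SIGLEC1, RN7SK, TP53INP2, MIR22HG, NUPR1, SNORA21, HLA-DRB5, MIR6501, HYAL3 and HLA-DRB6, and the largest mean falls EGR1, MKI67, CASC5, KIF14, CDK1, KIAA0101, ETV5, MYBL2, ASPM and DLGAP5. The mean SIGLEC1 call ended in 6 of 19 alternatives (adjusted p up to 0.069), and in MOLM-13 SIGLEC1 was high in replicate 1 of the knockdown alone (33.9 against 1.03 TPM in replicate 3), while RN7SK did not pass in NOMO-1 (0.89, adjusted p = 0.14). For the mean effect camera called 9 lists. They were mitosis (39 of 39 lower, adjusted p = 4.2e-21), DNA replication (42 of 42 lower, 1.3e-19), recombination and Fanconi repair (30 of 32 lower, 1.9e-12) and MYC targets (27 of 42 lower and 2 higher, 1e-06), then the MLL-fusion programme (15 of 20 lower and 1 higher, 0.00044) and m6A machinery (10 of 18 lower and 1 higher, 0.01). Upwards were azurophil granule (8 of 10 higher and 1 lower, 0.0012), ER chaperones (13 of 20 higher and 4 lower, 0.0057), which passed in NOMO-1 and not in MOLM-13, and cholesterol synthesis (12 of 20 higher and 2 lower, 0.015). The MLL-fusion programme, m6A machinery and cholesterol synthesis passed in MOLM-13 and not in NOMO-1. For the m6A machinery the difference between lines did not pass (camera adjusted p = 0.68). With median-of-ratios scaling it passed in both lines (0.047 in NOMO-1 and 0.037 in MOLM-13). With an estimated correlation the smallest adjusted p of any list was 0.62.

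**Figure D4:**
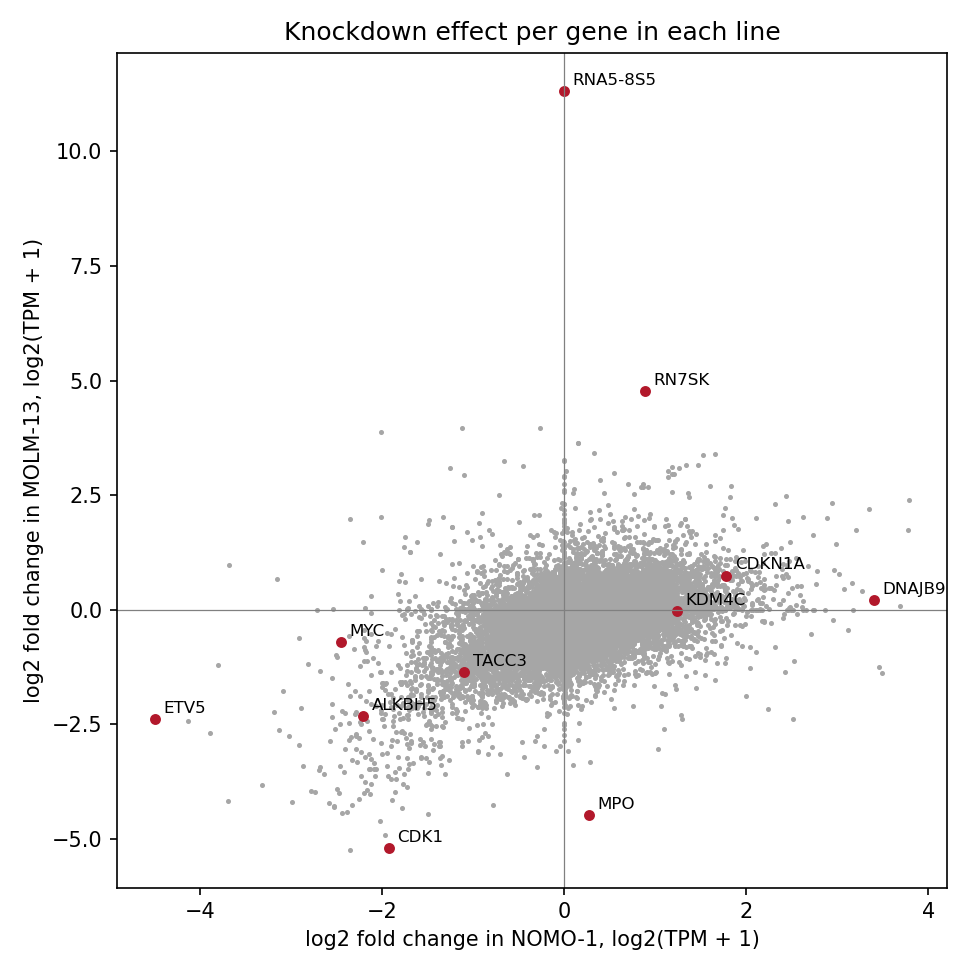
Log2 fold change after ALKBH5 knockdown in NOMO-1 (horizontal axis) and MOLM-13 (vertical axis), both on log2(TPM + 1), for each of the 14302 genes, with named genes in red. CDK1 and ETV5 lie low in both lines, and MPO is low in MOLM-13 (-4.48).

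The test of the difference asked where the lines responded differently. MYC fell more in NOMO-1 (difference -1.74, SE 0.29, adjusted p = 0.0084), and KDM4C rose more there (1.26, SE 0.17, adjusted p = 0.0051). Genes with the smallest p included MFAP4, MPO and SLC38A1, which were at -3.04, -4.48 and -3.43 in MOLM-13 and at 1.03, 0.27 and -0.3 in NOMO-1 (MPO under 1 TPM there), and IGFBP4, which fell by 1.76 in NOMO-1 and rose by 1.37 in MOLM-13. Camera called 9 lists for the difference. Relative to other genes, mitosis and DNA replication genes (which fell less in NOMO-1), MLL-fusion genes and ER chaperones had the higher value in NOMO-1. Interferon-stimulated genes, NF-kB genes, oxidative phosphorylation, cholesterol synthesis and ribosomal proteins had it in MOLM-13. The NF-kB call ended with median-of-ratios scaling (adjusted p = 0.21). The calls of interferon-stimulated and NF-kB genes rest on MOLM-13 shALKBH5 replicate 1. Their medians against the controls were 2.66 and 2.45 there, and -0.62 and -0.51 in replicate 3. The median of oxidative phosphorylation genes was 0.05, against camera's direction. By the deposited values cholesterol synthesis genes rose alike, with medians of 0.28 in NOMO-1 and 0.27 in MOLM-13, so there their call comes mainly from the other genes. With median-of-ratios scaling the medians were 0.1 and 0.61, so this reading depends on the scaling. With an estimated correlation the smallest adjusted p was 0.76. The difference passed for 4946 genes, 4245 with the larger value in NOMO-1 and 701 in MOLM-13 (85.8%), and with median-of-ratios scaling for 5132, of which 2631 were larger in NOMO-1 (51.3%). 3326 passed under both scalings in the same direction. The count ranged from 1635 without MOLM-13 shNS replicate 1 to 9661 without MOLM-13 shALKBH5 replicate 1.

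The 2 control lines were compared to describe them. NOMO-1 controls had more TPSAB1, CLEC2B, IL32, LOC100506159 and GTSF1, with 818, 1180, 518, 155 and 168 TPM on average, of which TPSAB1 and LOC100506159 were listed at 0 in both MOLM-13 controls. MOLM-13 controls had more PDLIM1, MPO, YBX3 and FLT3, a receptor tyrosine kinase, with 508, 420, 194 and 233 TPM against values under 1 TPM in NOMO-1. Between controls 8556 genes passed, 5812 higher in NOMO-1 and 2744 higher in MOLM-13 (67.9%), and 9430 with median-of-ratios scaling (4933 and 4497, 52.3%).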

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

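All tests weighed here were chosen after the results were seen, while the test of the difference between lines and its lists were set before. Values that differed between the lines by that test, under both scalings, are given first.

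The difference of the knockdown effects passed the threshold for 4946 genes, and for 3326 under both scalings in the same direction. For lists, in log2 units relative to other genes and as NOMO-1 minus MOLM-13, it was 0.83 for mitosis, 0.68 for DNA replication, 0.8 for the MLL-fusion programme, -1.25 for interferon-stimulated genes, 0.78 for ER chaperones, -0.37 for oxidative phosphorylation, -0.49 for cholesterol synthesis and -1.08 for cytosolic ribosomal proteins. None of these lists passed with an estimated correlation, where the smallest adjusted p was 0.76. Before other genes were subtracted, the mean difference was 0.03 for oxidative phosphorylation and -0.09 for cholesterol synthesis. By the deposited values, then, these results come mainly from the other genes. With median-of-ratios scaling the median differences of these lists were -0.47 and -0.68, so this reading depends on the scaling. In MOLM-13 the oxidative phosphorylation median against the controls was 0.11 in shALKBH5 replicate 1 and -0.17 in replicate 3. The interferon value rests on MOLM-13 shALKBH5 replicate 1, where the members' median against the controls was 2.66, while it was -0.62 in replicate 3. For single genes the difference was -1.74 for MYC, 1.26 for KDM4C, 4.07 for MFAP4, 4.75 for MPO, 3.14 for SLC38A1 and -3.13 for IGFBP4. MIR4482 (2.86) was listed at 0 in all MOLM-13 libraries. MIR6732 (-3.25), RNA5-8S5 (-11.32) and MIR4648 (-2.3) were listed at 0 in all libraries but those of MOLM-13 shALKBH5, and RNU4-1 (-5.1) was listed at 0 in the MOLM-13 controls and the NOMO-1 knockdown libraries, so these 5 values are fitted differences on log2(TPM + 1), not folds. Of 154 named genes, 75 passed the test of the difference under both scalings.

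For the mean effect, a fit with terms for knockdown and line alone passed 3917 genes, where the fit of the 4 groups passed 7256. Of the splits of the 8 libraries into 4 and 4 with 2 libraries of each line on each side, the highest other gave 16 genes, and these 18 splits are too few for a share under 0.05.

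Mitosis genes fell in both lines, 39 of 39 past the threshold in each. A fixed TPM sum would lower them where other transcripts took a larger share, but with median-of-ratios factors the upper quartile of the members' mean effect was still -2.31. A bias by transcript length also does not account for the fall, since the upper quartile of the members minus their 200 nearest genes by length was -2.21. Whether the lower transcripts come from ALKBH5 loss or from another effect of this hairpin stays open, since only 1 hairpin was used. Division itself was not analysed here, so a lower share of dividing cells is a hypothesis.

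Structural RNAs without a poly(A) tail rose in MOLM-13 shALKBH5, with 16 of 26 past the threshold and a median log2 fold change of 1.76. In NOMO-1 the median of the same RNAs was 0.01, with an upper quartile of 0.79 under the lower quartile of 0.91 in MOLM-13, which argues against a rise of the same size in both lines. Among the RNAs measurable in NOMO-1, by 4 definitions (10 to 17 RNAs), the NOMO-1 median was -0.27, 0.1, 0.22 or 0.91 and each upper quartile stayed under the lower quartile in MOLM-13; the share of small structural RNA went from 0.0282% and 0.0231% to 0.0453% and 0.0549%, so a smaller rise in NOMO-1 stays open. Histone genes, whose replication-dependent mRNAs lack a poly(A) tail, had a median of 0.84 in MOLM-13 although DNA replication genes fell, as less complete poly(A) selection needs. A change of these genes themselves could give this too, so it does not decide the question. The 95% bootstrap interval over 47 genes was 0.62 to 1.26, with genes taken as independent. Of the 47, 24 were higher and 0 lower in MOLM-13, and 16 and 11 in NOMO-1 (median 0). The looser filter looked at first gave 0.76 over 57 genes in MOLM-13. Not all RNAs without a tail rose alike, since the snoRNA share went from 1.83% and 1.82% to 1.77% and 2.39%. Of the ribosomal RNAs, RNA18S5 rose by 1 without passing (limma adjusted p = 0.14). RNA28S5 (1.65, adjusted p = 0.044), RNA45S5 (3.24, 0.0039) and RNA5-8S5 (listed at 0 in the controls, 0.00011) passed. Poly(A) selection and a change caused by the knockdown in MOLM-13 alone both stay open. By transcript length, the median log2 fold change in MOLM-13 was -0.16 for the shortest class of genes and -0.37 for the longest. In NOMO-1 these medians were 0.1 and 0.12. Whether a bias by transcript length adds to the rise of the structural RNAs in MOLM-13 was not tested, so it stays open too.

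Interferon-stimulated genes were higher than both controls for 36 of 36 members in MOLM-13 shALKBH5 replicate 1, with a median log2 difference of 2.66 (quartiles 1.64 and 3.78), and for 6 of 36 in replicate 3. The median in replicate 3 was -0.62 (upper quartile -0.09), which argues against a response shared by the knockdown libraries of this line. Lymphoid, erythroid and megakaryocyte cells are argued against by their markers: the highest gain of 38 such markers over every other MOLM-13 library was 0.39 on the log2 scale (GP1BA). Markers of monocytes, macrophages or dendritic cells were not part of this test, so such cells stay open. Among macrophage genes, SIGLEC1, CTSB and CTSD stood higher in this library (33.9, 241 and 317 TPM) than in replicate 3 (1.03, 118 and 186 TPM). CD68 stood lower, at 255 and 297 TPM. The rise of SIGLEC1 may be part of the interferon pattern itself, so it does not mark such cells. What raised the interferon-stimulated genes in that library alone stays open.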

How the results depend on the processing

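The alternatives were set before the data were examined. Protein-coding genes alone, rescaled, and the values of list members without a MOLM-13 shALKBH5 library were added afterwards. TPM hides depth, so which calls depth limits is unknown. Of 222 gene results, 165 kept their side of the threshold, and their direction where they passed it, under every alternative run for them (17 to 20 each), as did 48 of 63 list results outside the estimated correlation and fry. In settings where neither value passed, the direction turned for 7 gene and 18 list results, FTO in NOMO-1 and the immediate-early list in MOLM-13 among them. The count-model test was not run, since TPM gives no reads. Where a value moved, the cause was not tested.

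The number of list calls, 28, was 0 with an estimated correlation (smallest unadjusted p 0.053), while fry, which compares a list with no other genes, called 9 in NOMO-1, 7 in MOLM-13 and 10 for the mean. The same-direction overlap of 2387 became 3680 with median-of-ratios scaling and 3606 with quantile scaling. Library weights gave 9712 genes in NOMO-1 and 2818 in MOLM-13 (weight 0.101 for each MOLM-13 shALKBH5 library), and MOLM-13 alone gave 1684. Leaving out 1 library, where the lone library of a group is assumed to vary like the others, gave 3490 to 9745 genes in NOMO-1, 2665 to 9439 in MOLM-13, 5247 to 10212 for the mean, 1635 to 9661 for the difference, 6480 to 11202 between controls, 1249 to 4677 for the overlap and 28 to 31 list calls. ALKBH5 ranged from -2.25 to -2.16 in NOMO-1, -2.48 to -2.16 in MOLM-13 and -2.35 to -2.18 for the mean.

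With a value past the threshold on either side, directions turned for YTHDF2 in NOMO-1 with median-of-ratios scaling (-0.16), KDM4C in MOLM-13 with median-of-ratios (0.3) and quantile scaling (0.35), and, without MOLM-13 shALKBH5 replicate 1, for the interferon-stimulated (-0.22) and NF-kB lists (-0.49) in MOLM-13 and for AXL in MOLM-13 (-0.82) and the mean (-0.36). The AXL difference was then 0.92. Without MOLM-13 shALKBH5 replicate 3 these lists were at 2.83 and 2.61, and AXL at 1.01, 0.55 for the mean and -0.91 for the difference.

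In MOLM-13 the deviations of same-numbered libraries had a correlation of 0.06 over genes, with 2 pairs, so the numbers were not taken to pair them. The replicate block gave 6534 genes in MOLM-13, 6699 in NOMO-1, 7754 for the mean, 5661 for the difference and 28 list calls. No paired analysis was possible in NOMO-1 because its groups share a single number.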

Other observations

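The gene groups below and the tests on them were chosen after the results were seen.

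Genes of the MHC class II pathway, which presents peptides to T cells, were higher after knockdown in both lines. The 5 measured members were HLA-DRB5, HLA-DQA1, HLA-DMB, CD74 and the regulator CIITA, so not all encode peptide-presenting chains. All 5 passed limma's test in MOLM-13 and 4 of 5 in NOMO-1, with 0 lower. HLA-DRB5 values are uncertain, because reads can be assigned to another HLA-DRB copy. CD74, the invariant chain, rose from 93.1 ± 4.2 to 207 ± 0.14 TPM in NOMO-1 (SD, n = 2; log2 fold change 1.15, adjusted p = 0.025) and from 189 ± 3.5 to 672 ± 330 TPM in MOLM-13 (1.73, adjusted p = 0.0064), and HLA-DQA1 in NOMO-1 was at 1.2 (adjusted p = 0.32). In MOLM-13 the values of CIITA, CD74 and HLA-DQA1 were higher in replicate 1 (17.1, 905.7 and 28.4 TPM) than in replicate 3 (9.19, 438.2 and 2.59 TPM). Without replicate 1 the median log2 fold change of the 5 members was 1.45 in place of 2.67. With MOLM-13 fitted alone 2 of 5 passed. Camera over the 3 lists of this part, whose members include genes already seen to change, gave adjusted p = 0.093 in NOMO-1 and 0.00011 in MOLM-13, and adjusted p = 0.47 and 0.18 with an estimated correlation. With median-of-ratios scaling the camera adjusted p was 0.034 and 0.003. CIITA, the regulator that switches these genes on, rose in both lines, by 0.86 in NOMO-1 (adjusted p = 0.035) and 2.67 in MOLM-13 (adjusted p = 0.00078). It is 1 of the 5 members counted, so whether it drives the other 4 stays open, and lowering CIITA together with ALKBH5, which was not analysed here, would decide it.

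Of 7 measured genes expressed in macrophages, C1QA the only complement gene among them, 5 rose in NOMO-1 and 3 in MOLM-13 (0 lower), and APOE and CTSB passed in neither line. The values were C1QA from 3.83 ± 0.042 to 31.8 ± 0.78 TPM in NOMO-1 (log2 fold change 2.76, adjusted p = 0.00032), CTSD at 0.98 and 1.8 and CD68 at 1.67 and 0.92 in NOMO-1 and MOLM-13. In MOLM-13, replicate 1, the library with high interferon-stimulated genes, stood above replicate 3 for SIGLEC1 (33.9 and 1.03 TPM), CTSB (241 and 118 TPM) and CTSD (317 and 186 TPM). Camera gave adjusted p = 0.015 and 0.00042, and 0.32 and 0.18 with an estimated correlation.

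The falls of ETV4 and ETV5 prompted a look at other genes induced by MAPK signalling. Outside these ETV genes, 4 of 6 members fell in NOMO-1 (SPRY2, SPRY4, DUSP4, DUSP6) and 3 of 6 in MOLM-13 (SPRY4, DUSP4, DUSP6), where SPRY2 was at -0.68 (adjusted p = 0.2). Lower MAPK output may lie behind this, but the test set for it needed 4 in each line and the smaller count was 3, so it stays undecided. The MOLM-13 shALKBH5 libraries differed here too. SPRY2 stood at 41.6 TPM in replicate 1 and 16.7 TPM in replicate 3, against 43.9 and 41.9 TPM in the controls. PHLDA1 stood at 15.1 and 1.92 TPM against 6.88 and 5.34 TPM.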
